A study of Drosophila melanogaster with 4 samples.

How the data were processed

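Head nuclei of mixed adult flies were profiled in 2 H4K8ac ChIP libraries and 2 input libraries. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, flies were grown in population cages, heads were collected by sieving, tissue was treated with formaldehyde, and chromatin was sheared by sonication in SDS before immunoprecipitation. Nothing in the labels says whether the replicates came from separate fly collections, so the spread between them can be technical. No sex is given in the labels.

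Each deposited list holds regions with a start, an end and 1 score, and per the file headers the coordinates are those of FlyBase release 5. Bowtie 0.12.7 is named in the submitters' processing notes. The region caller, its threshold, the filters and the way the replicates were combined are not given in the sources used here. The deposited score was the authors' own value for each region and was used as deposited. Per the labels, each input library served as the control for 1 ChIP library. The input libraries had no list of their own here, so no background could be measured in them. The combined set also held 1 region marked as depleted, which was kept out of the cluster counts.

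The scale of the score is not stated in the labels or headers, and it was examined in the values. When 2 was raised to the score, 100% of the clusters of each replicate and 99.8% of the combined set gave a constant multiplied by a ratio of whole numbers. The relative tolerance was 1e-13. The largest denominator searched was 50000, for ratios to the most frequent score before the constant was set. The constants were 1.03 in replicate 1, 1.22 in replicate 2 and 1.12 in the combined set. The same reading with base e or base 10 succeeded for at most 0.871% of the clusters. Scores were therefore read as log2 of a scaled ratio of ChIP to input counts. The whole numbers are in lowest terms, so a shared factor of the counts is lost and they can lie below the counts. For some long clusters they can also lie above them. The denominator read for the 99.9 kb cluster at 3L 22301130 to 22401045 of the combined set was 214615. This is more than the inferred autosomal density of 192 input reads per kb would give. Densities per kb were taken from clusters of at least 2000 bp as the median of the upper mode, in which the counts were taken to share no factor. These densities are inferred, refer to called clusters alone and are used in the comparison of X with the autosomes and in the closing observations.

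Read totals were not given, so depth is unknown for all libraries and no error of a single score is reported. Binomial intervals are exact Clopper-Pearson intervals for shares of clusters at the 95% level. They cover counting error alone, and neighbouring clusters are not independent. Bootstrap intervals resampled blocks of 1 Mb 1000 times.

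Clusters were counted as shared when they overlapped by at least 1 bp. Chance overlap came from 1000 seeded circular shifts of replicate 2 along each arm, and the coverage of long domains was set against 1000 shifts of the other replicate in the same way. Correlations of scores used clusters that overlapped one to one. Coverage was taken over the sequence lengths in the file headers. The ratio of X to the autosomal arms 2L, 2R, 3L and 3R was tested in each list with 10000 seeded circular shifts along the concatenated arms, two-sided. The same test was run for each of the 5 arms against the others, with Benjamini-Hochberg adjustment within each list. Score differences were tested with all circular shifts of the arm labels along the ordered clusters. The threshold was 0.05. Where the text gives 1 p for both replicates, it is the larger one.

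The methods were tested on simulated data. With 8135 simulated clusters, 67.5% were found again. The expected value was 67.8%, from the clusters built to be shared plus the chance overlap of the rest. Both values used the same overlap step, so this checks the bookkeeping alone. In 200 simulated sets of 8631 clusters on random arms, thinning X to 0.6 of its clusters gave a mean ratio of 0.600, and 100% of the sets passed the threshold of 0.05. Without thinning, 8.5% of the sets passed, so the p-values of the X test were somewhat too small in that setting. The simulated clusters lay at random places, whereas the real ones are unevenly spread. How far the p-values are off in the data was therefore not measured. Scores built from known counts for 8148 clusters were read as whole ratios in 100% of cases. The simulated input density of 90 per kb was recovered as 90.3 over 4737 clusters. Of random scores, 0.0491% were read as whole ratios.

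Tests, groups, alternatives and the rule for named regions were fixed before the data were examined. Alternatives fixed at that stage kept the upper 50% of each list by score, merged clusters less than 500 bp apart, left out clusters under 1000 bp, asked for 50% overlap, left out each replicate, used the combined set, and trimmed 1 Mb from each arm end. The rule named the 10 highest-scoring and the 10 longest clusters of the combined set by coordinates. The score difference between X and autosomes, the 1 Mb windows and arm ends, the class of clusters of 10 kb or more, the regions high in both replicates, the stretches without clusters, the shifts for long domains and for clusters found again, and all work with whole-number ratios were chosen after the data were examined.

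Coverage of transcription start sites and tests of 24 gene lists had also been planned. The gene table at hand is on release 6 and the clusters are on release 5, and coordinates were not converted. These analyses and their alternatives were therefore not run, and no gene is named. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.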

Results

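Acetylation of histone H4 at lysine 8 (H4K8ac), a modification found at active chromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in head nuclei of mixed adult Drosophila melanogaster. The flies were of the wild-type strain Oregon-R. The series holds 4 samples, made up of 2 H4K8ac ChIP libraries and 2 input libraries. Each ChIP library was represented by 1 list of regions enriched over its own input, called clusters here, and another list held the authors' combined replicate set. The input libraries entered only through these lists. No treatment or other tissue is part of the design, so the comparisons were between the replicates, between the replicates and the combined set, and between chromosome arms. Sequencing depth was unknown, because the lists hold regions and scores and no read totals. Coordinates are those of FlyBase release 5, and means are given ± SD over the 2 ChIP replicates.

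About 1 base in 4 of the major chromosomes of head nuclei lay in an H4K8ac cluster. Replicate 1 had 8148 clusters covering 31.1 Mb, and replicate 2 had 8140 clusters covering 29.6 Mb. Together with chromosome 4, the 5 large arms were covered to 25.2% ± 0.838 (SD, n = 2). Most clusters were short, with median lengths of 2180 and 2114.5 bp, and the shortest in each list measured 1301 bp. A small class of domains of at least 10 kb, 498 in replicate 1 and 463 in replicate 2, held 28.1% ± 0.795 of the covered bases (SD, n = 2).

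Enrichment over input was modest in most clusters and higher in the long ones. The authors' score, read here as a log2 ratio of ChIP to input, had a median of 0.66 in replicate 1 and 0.65 in replicate 2, or 1.58-fold and 1.56-fold. Clusters of at least 10 kb had median scores of 0.89 and 0.86, against 0.65 and 0.64 for shorter ones. Length and score rose together across clusters, with Spearman's rho of 0.634 and 0.641. Clusters are not independent replicates, so no p-value is given for this relation.

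The replicates placed most of the acetylated chromatin in the same positions. They shared 23.9 Mb, which was 76.8% of the bases in replicate 1 clusters and 80.5% of those in replicate 2 clusters. Of the replicate 1 clusters, 6335 (77.7%, exact 95% binomial interval 76.8 to 78.6) overlapped a replicate 2 cluster by at least 1 bp. In the other direction, 6575 clusters did so (80.8%, interval 79.9 to 81.6). The long domains of replicate 1 were covered to 93.9% of their bases by replicate 2 clusters, against a mean of 26.5% and a maximum of 46.2% after circular shifts. For those of replicate 2 the value was 95.7%, against a mean of 27.5% and a maximum of 43.0%. Clusters seen in a single replicate were shorter and weaker. In replicate 1 they had a median of 1590 bp and a score of 0.60, against 2729 bp and 0.69 for those found again. In replicate 2 the values were 1572 bp and 0.58, against 2471 bp and 0.66. After circular shifts of the other replicate, clusters not found again had mean medians of 2071 bp and 0.66 in replicate 1 and of 2036 bp and 0.64 in replicate 2. After shifts, 38.5% of replicate 1 clusters were found again on average, against 77.7% observed. The groups not found again thus differ in size, and the shifts cannot say how much of the difference the 1 bp rule itself gives.

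The Jaccard index of covered bases was 0.647, while circular shifts of replicate 2 along each arm gave a mean of 0.151 and a maximum of 0.227. The one-sided p was 0.001, the smallest that 1000 shifts can give, and it describes these 2 libraries. After such shifts, 38.5% of replicate 1 clusters still touched a replicate 2 cluster on average. Required to overlap reciprocally by at least 50%, 52.5% of the clusters of each replicate were shared. Scores at 3562 pairs of clusters that overlapped one to one had a Spearman's rho of 0.670 (bootstrap 95% interval 0.640 to 0.697) and a Pearson's r of 0.715 (0.691 to 0.737), both across clusters. Within the autosomal arms rho was 0.621 (0.593 to 0.648), and within X it was 0.484 (0.394 to 0.573). Replicate 1 scores lay above replicate 2 scores by a median of 0.02, and the differences had an SD of 0.11.

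In the combined replicate set, more of the genome was called as clusters than in either replicate. It listed 10650 clusters over 47.8 Mb, or 39.7% of the arms, with a minimum length of 1001 bp and a median score of 0.46. Nearly all replicate clusters, 99.8% of each list, overlapped a combined cluster. The combined set stands for the same replicates and covers more of the genome, so this overlap is no independent support. Of the combined clusters, 4103 (38.5%) were found in both replicates, 2531 (23.8%) in one and 4016 (37.7%) in neither. The clusters found in both replicates had a median of 5427 bp and held 75.3% of the combined bases. Those found in neither had a median of 1303 bp and a score of 0.41, and held 12.4% of the bases. Among them, 1997 were shorter than 1301 bp, the minimum length in the replicate lists. When those shorter than this minimum were left out of the combined set, a step chosen after seeing the data, 23.7% of its clusters were found in neither replicate.

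Within each list, the X chromosome carried less H4K8ac cluster coverage than the large autosomal arms, but not at about equal inferred read density. Clusters covered 16.7% ± 1.27 of X and 27.5% ± 0.75 of the autosomal arms (SD, n = 2). The autosomal arms lay close together, at 26.3% ± 0.734 for 2L, 27.7% ± 0.831 for 2R, 26.4% ± 0.345 for 3L and 29.4% ± 1.06 for 3R. X had 58.3 ± 2.05 clusters per Mb against 70.6 ± 0.410 on the autosomal arms. Long domains numbered 1.43 per Mb of X in each replicate against 4.82 and 4.46 per Mb of the autosomal arms. Clusters on X nevertheless had higher scores, with a median of 0.79 ± 0.04 against 0.63 ± 0.01 (SD, n = 2). The input density inferred from the scores was lower on X, at 0.593 ± 0.0416 of that on the autosomal arms (SD, n = 2). At about equal inferred density, X of the combined set against the autosomal arms of the replicates, these directions turned. With clusters of at least 1301 bp, X was then covered to 30.2% against 27.5%, and its median score was 0.56 against 0.63. Long domains then numbered 5.93 per Mb of X against 4.82 and 4.46 per Mb of the autosomal arms. This sets lists side by side that differ in minimum length, and X still had the higher density, 114 input reads per kb against 91.9 and 101. The autosomal arms themselves moved the same way between the lists, to 41.9% coverage and a median score of 0.44 in the combined set. The turn therefore does not show that X is covered more at equal density.

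The ratio of X to autosomal coverage was 0.628 in replicate 1 (two-sided circular-shift permutation p = 0.0034, adjusted p = 0.0170 over 5 arms by Benjamini-Hochberg). It was 0.586 in replicate 2 (permutation p = 0.0056, adjusted p = 0.0280) and 0.776 in the combined set (p = 0.0043, adjusted p = 0.0215). No autosomal arm passed the threshold of 0.05 in either replicate, with adjusted p from 0.520 to 0.852 in replicate 1 and from 0.576 to 0.740 in replicate 2. Among the upper 50% of clusters by score, which favour X, the mean ratio was 0.790 and the larger p was 0.328. The score difference, tested after it was seen, was 0.17 in replicate 1 (bootstrap 95% interval 0.15 to 0.19) and 0.14 in replicate 2 (0.13 to 0.14). Shifts of the scores along the clusters gave two-sided p of 0.00172 and 0.00271. In the upper 50% by score the mean difference fell to 0.07. These p-values describe each library, since 2 replicates cannot pass an exact sign test (smallest p = 0.5).

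Chromosome 4 and the heterochromatic sequences were nearly free of clusters. Each replicate had 4 clusters on chromosome 4, a small chromosome rich in heterochromatin, and they covered 0.555% ± 0.00659 of it (SD, n = 2). The combined set had 14 clusters there, covering 1.70%. The separately assembled heterochromatic sequences of 9.28 Mb in all were covered to 0.187% ± 0.0197 (SD, n = 2), with 9 and 10 clusters. No replicate cluster lay on the 39.1 Mb of unplaced sequence. No input density was inferred for any of these sequences and mappability was not examined. Few calls there may therefore reflect few usable reads rather than little acetylation, and the lists cannot tell these apart.

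**Figure D1:**
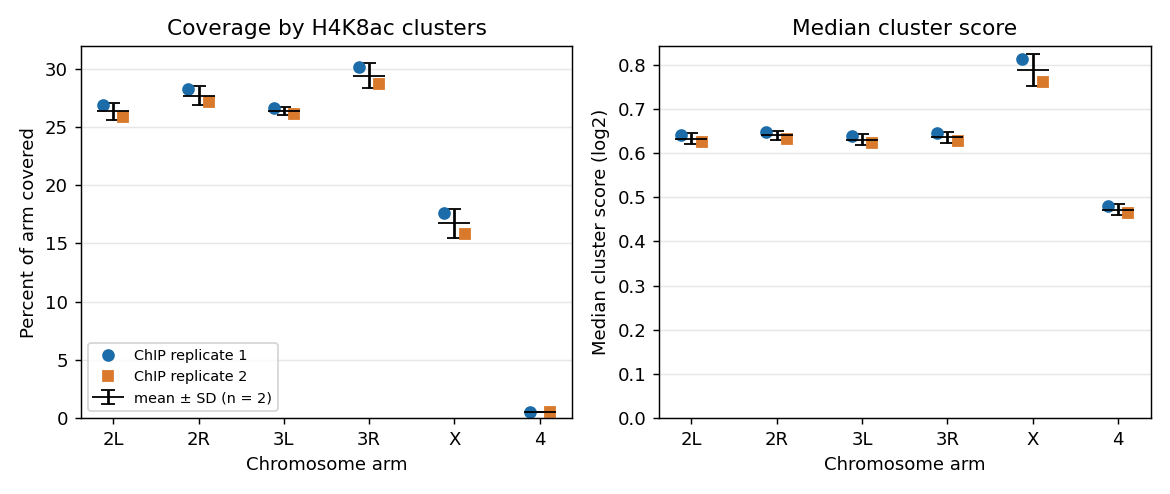
Percent of each chromosome arm covered by H4K8ac clusters (left) and median cluster score on a log2 scale (right) for ChIP replicates 1 and 2, with horizontal lines and bars for the mean ± SD (n = 2). X lies at 16.7% coverage against 26.3% to 29.4% on the large autosomal arms, while its median score of 0.79 is above theirs. Neither difference was seen when X of the combined set was set against the autosomal arms of the replicates. X then had the somewhat higher inferred input density.

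Within arms, acetylation varied from window to window in nearly the same way in both replicates. Across 117 full windows of 1 Mb, coverage had a median of 25.4% with quartiles of 17.3% and 32.1%. The replicates differed by a median of 1.22 percentage points and at most 5.58. Pearson's r across the windows of all arms together was 0.989, which includes differences between arms. No correlation was taken within single arms. The most covered window was 3L 10000001 to 11000000, at 59.0% ± 0.366. It was followed by 3R 22000001 to 23000000 at 51.8% ± 0.769 and 3R 23000001 to 24000000 at 46.2% ± 2.93 (SD, n = 2). The least covered was 3L 23000001 to 24000000, at 0.176% ± 0.0587, next to 3L 22000001 to 23000000 at 45.7% ± 0.0809. Coverage was low at the centromere end of most arm sequences. The 1 Mb at this end was covered to 1.28% ± 0.0296 on 2L, 1.26% ± 0.258 on 2R and 3.02% ± 0.0349 on X. On 3L no cluster lay in it. The arm 3R differed, with 27.7% ± 0.0138 at its centromere end. The separately assembled heterochromatic sequences, among them 2.52 Mb of 3R covered to 0.0794%, lie outside these ends. The value for 3R therefore does not show clusters next to its centromere. Mappability near the centromeres was not examined, so low coverage there is a statement on calls. The 1 Mb at the telomere side was covered to between 21.1% on 2R and 37.1% on 3R.

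**Figure D2:**
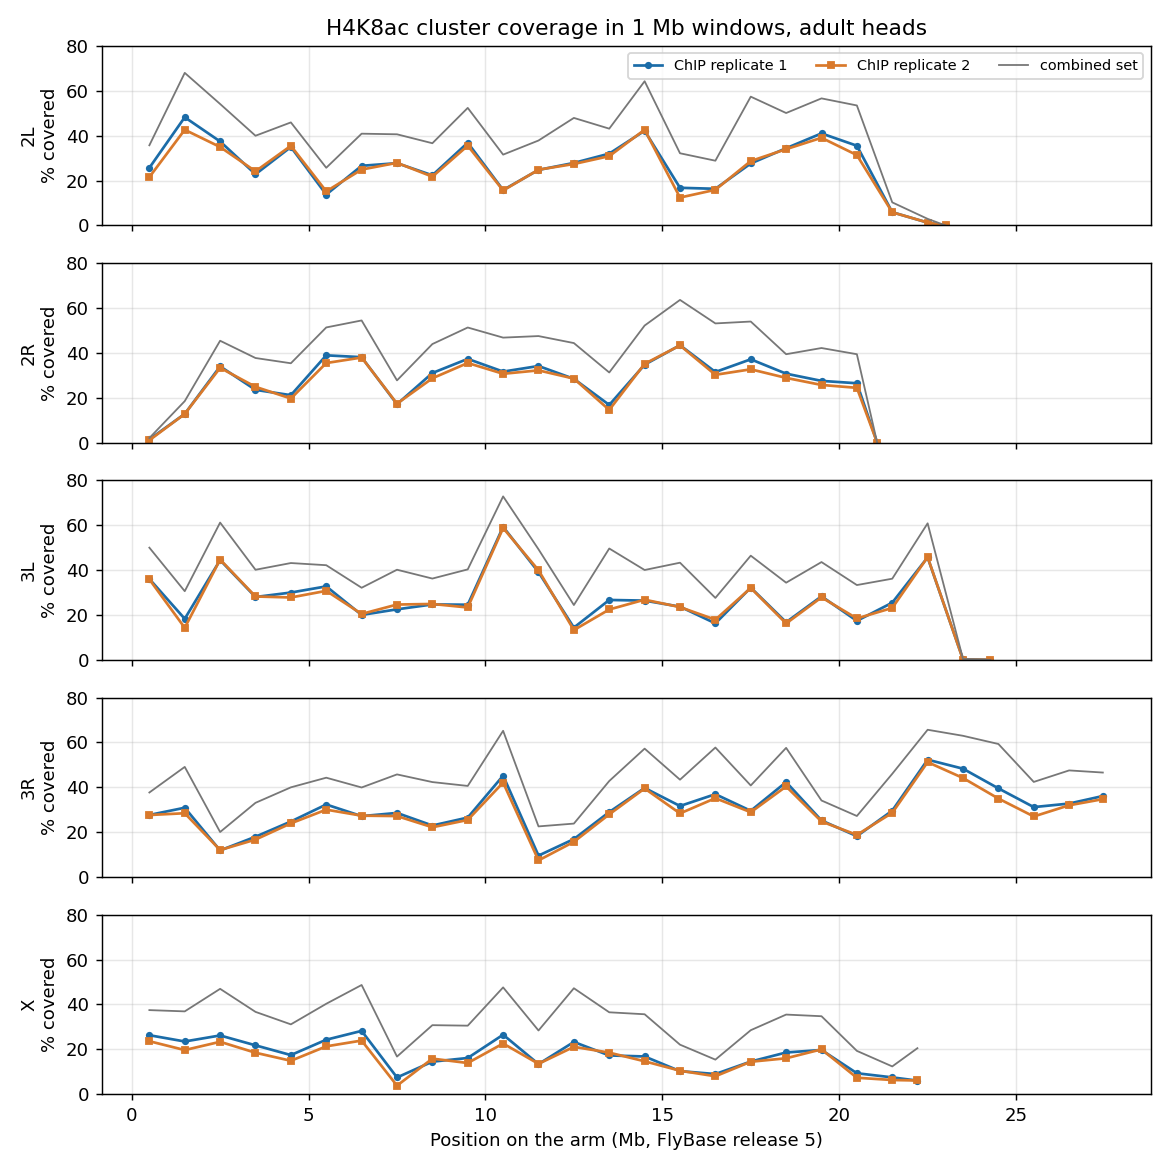
Percent of each 1 Mb window covered by H4K8ac clusters along the 5 large arms, for ChIP replicate 1 (circles), ChIP replicate 2 (squares) and the combined set (grey line); the last window of an arm is shorter. The replicates run together with a median difference of 1.22 percentage points. Coverage drops at the centromere end of the 2L, 2R, 3L and X sequences but not of the 3R sequence. Heterochromatic sequences assembled apart from the arms are not shown.

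The 10 longest domains of the combined set were covered almost throughout in both replicates and all autosomal. The longest spanned 130.1 kb at 3L 11325022 to 11455091, with a score of 0.90. It was followed by 117.1 kb at 3R 5694738 to 5811852, with a score of 1.07, and 99.9 kb at 3L 22301130 to 22401045, with a score of 0.86. Of the others, 4 were on 3L, at 19136947 to 19227579, 5177896 to 5265731, 3515472 to 3596693 and 749712 to 826824. The last of these, 77.1 kb long, had the highest score of the 10, at 1.20. The remaining domains lay at 3R 13746963 to 13833194, 2R 6911531 to 6994300 and 2L 7893865 to 7968213. Replicate 1 clusters covered between 86.7% and 98.6% of each of the 10, and replicate 2 clusters between 90.02% and 99.0%. The combined set stands for the same replicates, so this coverage is no independent check of the domains. The longest X cluster of the combined set measured 60.4 kb. Within this set the inferred input density was 114 reads per kb on X and 192 on the autosomal arms. The longest autosomal clusters of the replicates, at 91.9 and 101 reads per kb, measured 100.4 and 76.4 kb.

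**Figure D3:**
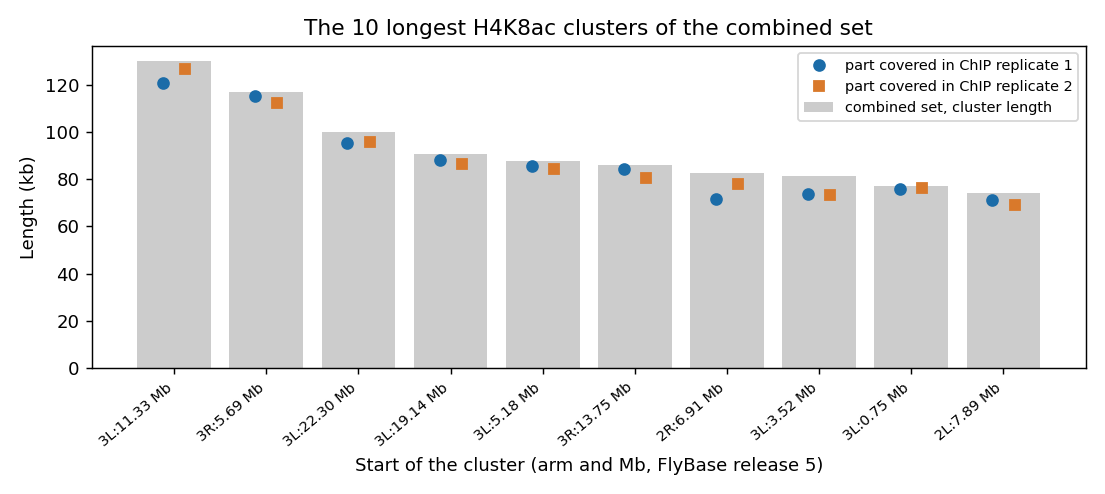
Length in kb of the 10 longest H4K8ac clusters of the combined set (grey bars) and the length covered by clusters of ChIP replicate 1 (circles) and ChIP replicate 2 (squares). Every domain is covered to at least 86.7% in both replicates.

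The 10 highest-scoring clusters of the combined set were of another kind, short and seen in neither replicate. They measured between 1001 and 1083 bp and scored from 1.75 to 3.62. The replicate lists held no region under 1301 bp, so clusters of this size could not appear there. The highest was X 2965028 to 2966029, at 3.62, followed by 2L 12940289 to 12941289 at 3.34. Clusters at 2R 5039500 to 5040500 and 3L 5105517 to 5106599 both scored 3.17. The others were 2L 2100463 to 2101463 at 2.97, 3R 16967457 to 16968465 at 2.75, 2R 20615463 to 20616496 and 3R 4435616 to 4436616 at 2.62, X 18648337 to 18649386 at 2.49 and 2R 4378117 to 4379117 at 1.75. By contrast, the highest score in a replicate list was 1.54 in replicate 1 and 1.38 in replicate 2.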

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

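The tests in this part were chosen after the results were seen, except the trimming of arm ends, which was planned although its reading was fixed afterwards, and the test on clusters of at least 5 kb, whose reading was fixed before its value was seen. All of them rest on cluster lists of 2 libraries and their combined set.

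The combined set held 1 region marked as depleted rather than enriched, a signal outside the measurements of enrichment. It lay at 3R 23406922 to 23408454, measured 1533 bp and had a score of -0.028. No replicate cluster overlapped it, and neither replicate list held a depleted region.

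X was covered less than the autosomal arms, yet its clusters scored higher. After 1 Mb was trimmed from each arm end, the mean ratio of X to autosomal coverage was 0.599. The lower coverage of X was thus also present outside these ends. The ends are too small a part of the arms for trimming to have removed the difference, so this is no test of a wider effect. Fewer reads on X may account for both sides of the pattern, if calling a region with fewer reads takes a higher ratio, which was not tested. By the whole-number reading, X in the combined set had 114 input reads per kb, somewhat above the 91.9 and 101 of the autosomes in single replicates. At these densities, with clusters of at least 1301 bp, X coverage was 1.098 times that of the autosomes and its median score was lower, with a difference of -0.076. The combined set has another minimum length and possibly other call settings, and no biological explanation was tested, so a difference in acetylation on X stays open.

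The input density itself was lower on X, at 0.593 ± 0.0416 of the autosomal density (SD, n = 2). In clusters of at least 5 kb, where counts are large, the ratio was 0.601 ± 0.0513. Both ratios rest on the upper mode of the densities, which leaves out clusters of low density. Their likeness therefore cannot decide whether clusters with low input counts were selected. More males than females among the flies could give a ratio between 0.5 and 0.75, but this cannot be told apart from other causes, because no sex is given in the labels. The density is inferred from called clusters alone, and mappability on X was not examined.

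The highest scores of the combined set may come from windows with very few reads. The whole numbers behind the 10 scores had input values of 1 in 8 clusters and 2 in the others, a median of 0.999 per kb, while 897 other clusters of at most 1100 bp had a 5th percentile of 13.0 per kb. Large counts reduced by a common factor were looked for among the others, where a share of 0.0223 of those 897 had an input value from 2 to 5. The 10 were picked for high scores, and a score limits which whole numbers can stand behind it. This share therefore cannot decide on reduction among the 10. Why such windows passed the authors' threshold stays open, and no biological explanation was tested.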

How the results depend on the processing

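Tests chosen after the results were seen are those of the score difference, the window permutation, X of the combined set against autosomes of the replicates, and the combined set cut to the replicates' minimum length. Of 12 alternative values of the 3 tested results, 9 kept their direction and their side of 0.05. At about equal inferred read density, with X of the combined set against autosomes of the replicates, the coverage ratio reversed to 1.098 and the score difference to -0.076. X then had the somewhat higher inferred density, and the lists differ in minimum length. The X to autosome coverage ratio weakened to 0.790 (permutation p = 0.328) in the upper 50% of clusters by score, a selection that by construction keeps more of the higher-scoring X clusters. In the other settings that ratio ran from 0.586 to 0.776, and the score difference from 0.07 to 0.17. Of 35 values without a test, 28 moved and 7 stayed within the spread or, for cluster counts, within 1.5 times, among them 6513.5 clusters per replicate and 7580 combined after merging. Taking the upper 50% by score by construction gave 4072.5 clusters and 22.0 Mb per replicate and 5325 clusters and 37.5 Mb combined. It also gave 70.6% and 73.5% of replicate 1 and 2 clusters shared, a rho of 0.518, and 36.4% of combined clusters in neither replicate. Coverage was then 15.2% of X, 19.3% of the autosomal arms and 0% of chromosome 4. Merging gave 41.7% of combined clusters in both replicates and 36.1% in neither. Overlap of at least 50% of the cluster lowered sharing to 69.8% and 73.8%, raised rho to 0.706, and left 28.8% of combined clusters in both and 42.5% in neither. Reciprocal overlap gave 52.5% and 52.5%, a rho of 0.741, 18.5% and 50.2%. At the replicates' minimum length, 48.2% of combined clusters were in both and 23.7% in neither. The combined set raised coverage to 32.5% of X, 41.9% of the autosomal arms and 1.70% of chromosome 4. The cause was not tested for merging, overlap or pooling. Leaving out clusters under 1000 bp removed nothing, and with 2 replicates the 10 values without one of them cannot leave the spread or end a call, so neither is counted or speaks to stability. The 17 alternatives for start sites and gene lists were not run for want of an annotation on the build of the clusters. No paired analysis was possible because the input libraries had no list here and each ChIP list was already called against its own input. Depth is unknown, so its limit on weak clusters was not measured.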

Other observations

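The regions, stretches and densities in this part were all chosen after the data were examined.

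Clusters strongly enriched in both replicates were found on X and on autosomes. Among clusters that overlapped one to one, the 10 with the highest score in the weaker replicate were on X in 4 cases. Of the rest, 3 were on 3R and the others on 2L. X held 16.5% of all such pairs. X scores ran higher in the replicates. Against autosomal scores of the replicates, X scores of the combined set, at a somewhat higher inferred input density, differed by -0.076. The first was X 6751736 to 6762252 in replicate 1, with a score of 1.42 ± 0.06, or 2.77-fold and 2.60-fold over input. It was followed by the 37.8 kb domain at 3R 27243551 to 27281320, at 1.39 ± 0.03, and by X 6230863 to 6239033, at 1.27 ± 0.03 (SD, n = 2). The others on X were 10262225 to 10267115, at 1.26 ± 0.15, and 1308753 to 1327620, at 1.23 ± 0.12. On 3R, a pair of neighbouring domains at 834565 to 872449 and 898691 to 910295 scored 1.23 ± 0.01 and 1.15 ± 0.02. The highest on 2L was 2747366 to 2753348, at 1.22 ± 0.02. None of these 10 is among the 10 highest scores of the combined set, which follows from those overlapping no replicate cluster.

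Long stretches of the arms held no cluster in either replicate. There were 110 such stretches of at least 100 kb, 20.1 Mb in all or 16.9% of the 5 large arms. Their share was highest on X, at 22.0% in 30 stretches, and lowest on 2R, at 13.5% in 15. These are calls of single replicates, in which the inferred input density on X was 0.593 of the autosomal one, and no such ranking was made at equal density. The longest, 3L 23144368 to 24543557, reached the centromere end of the arm over 1399 kb and held 1 cluster of the combined set. Within 3R, stretches at 2458894 to 2901552 and 12456368 to 12810865 measured 442.7 and 354.5 kb, and clusters of the combined set covered 0.542% and 0.0279% of them. On 2R, 481.4 kb at 1147933 to 1629290 were free of replicate clusters.

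Relative to the replicate mean, the combined set had 1.59 times as many clusters on X, 1.25 times as many on the large autosomal arms and 3.5 times as many on chromosome 4. The numbers behind the combined set were 2076, 8529 and 14 clusters. These gains set lists side by side that differ in minimum length, 1001 bp in the combined set and 1301 bp in the replicates. At 1301 bp or more, X of the combined set had 1623 clusters, against 1340 and 1275 in the replicates. On the autosomal arms, 1552 combined clusters found in neither replicate, 106 found in one and 1 found in both were shorter than 1301 bp. The replicates had 6795 and 6851 clusters there. Clusters too short for the replicate lists thus nearly match the autosomal gain in number, while X kept a gain without them. The input density of the combined set on autosomes was 0.996 of the sum of both replicates, and on X it was 0.991 of that sum. For ChIP reads on autosomes the value was 0.887.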
